A study of Mus musculus with 12 samples.

How the data were processed

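Total RNA from the spleens of 12 mice was measured on Affymetrix MOE430A 2.0 arrays, 1 array per mouse. The labels give 4 groups of 3 mice: Dusp1 wild-type and Dusp1 knockout mice, each without treatment (control) and 6 h after an intraperitoneal injection of lipopolysaccharide (LPS) at 10 µg per g of body weight. For each array 5 µg of RNA was labelled. Per the series' processing notes, the authors turned the scanned arrays into expression values with RMA in the R affy package, and the deposited values are an intensity per probe set on a linear scale. All of these values were whole numbers, from 6 to 15228, and 30.84% of them lay under 20. Array medians ran from 47 to 63, so the deposited arrays did not share 1 distribution. No version of the authors' software is given. Groups were taken from the sample titles, and the word knockout here means the label, since the Dusp1 signal gave no check of it. Signal over background and the number of arrays set the precision.

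The intensities were log2-transformed. Of the 22690 probe sets, 64 controls were left out and 22626 were tested. The platform's gene table gave 1 gene for 20380 of these, several genes for 691 and none for 1555. A gene was represented by its probe set with the highest mean over the 12 arrays, among those that name that gene alone and with sets ending in _x_at left aside where there was another. This gave 12393 genes, 4956 of them with over 1 probe set. A linear model with 4 group means was fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 2.722 prior degrees of freedom). Contrasts numbered 7: the LPS response in each genotype and its average, the genotype difference in controls, after LPS and averaged over both, and the interaction, which is the difference between the LPS responses. Each limma moderated test was two-sided, with Benjamini-Hochberg adjustment over the 22626 probe sets in each contrast and a threshold of 0.05. A value written after ± is limma's standard error of a log2 difference between groups of 3 mice. The averaged LPS response shares no chance error with the genotype difference after LPS or with the interaction in a design with equal groups, and was used wherever genes were sorted by their LPS response. A true difference confined to the LPS arrays of 1 genotype still enters it.

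Gene lists numbered 41 and held 890 written members, of which 768 were measured, 7 of them through a synonym. They covered proinflammatory cytokines, chemokines, anti-inflammatory and feedback regulators, interferon-stimulated genes, NF-kB pathway members, AP-1 and immediate-early genes, DUSP phosphatases, the MAP kinase pathway and the Toll-like receptor pathway. Further lists held acute phase and STAT3 targets, the enzymes of prostaglandin, nitric oxide and macrophage effector synthesis, coagulation and endothelial activation, MHC class I and immunoproteasome, MHC class II antigen presentation, complement and apoptosis. Metabolic and housekeeping lists were cell cycle and proliferation, ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia response, glucocorticoid response, heat shock and unfolded protein response, antioxidant and metal response, cholesterol and fatty acid synthesis, and extracellular matrix remodelling. Cell and tissue lists gave markers of B cells, plasma cells, T cells, NK and cytotoxic cells, neutrophils, monocytes and macrophages, dendritic cells, erythroid cells, platelets and megakaryocytes, mast cells and basophils, endothelium, stroma and smooth muscle, pancreas, adipocytes, and mesothelium and epithelium, and 1 list held sex-linked genes. Each list was tested on 1 probe set per gene with camera in limma at a preset correlation of 0.01, adjusted over the 41 lists of a contrast. The same test with an estimated correlation and fry (directional unless called mixed) were run beside it. Another 3 lists, of liver markers, of lung markers, and of nuclear-retained and splicing-factor transcripts, were added after seeing the data and served only as means per array.

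The comparisons, tests, 41 lists, most alternatives and the choice of genes to name were fixed before the data were examined. Named genes were, per contrast, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean above the 40th percentile of all probe sets (an intensity of 30.49) and no overlap between the groups of 3 arrays. To these came up to 4 called members of each list, and always Dusp1, Tnf, Il6, Il10, Il1b, Ccl2, Ccl3, Ccl4, Cxcl2, Ifng, Nos2, Ptgs2 and Socs3. Any other gene is said to be named after its values were seen. Genes called between genotypes were counted by their LPS calls in each genotype and averaged. The position of Dusp1 and its neighbours came from a RefSeq gene table on GRCm38.p6, used only for distances, with one-sided Fisher's exact tests. No gene was called in the averaged genotype contrast, so the 100 genes with its smallest p took their place, a choice made after seeing that.

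The steps were tested on simulated data drawn with these group sizes and spreads, for the genotype difference after LPS. A change of 0.5 on the log2 scale was recovered for 1 of 67 genes, a change of 1 for 21 of 67 and a change of 2 for 50 of 66, and 0 of 12193 unchanged genes were called. The chemokine list with its 26 members shifted by 1 was called, with 0 of the other lists. Each probe set was drawn independently, without the correlation between genes of the real arrays (estimated at 0.80 within the pancreas list). So these counts of 0 do not measure how often genes or lists are falsely called in the real arrays. No 2 arrays held identical values.

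Alternatives tried were an intensity trend with a robust prior, cyclic loess between arrays, a shift of every array to 1 median, leaving out dim probe sets, array quality weights, the mean of a gene's probe sets, leaving out sets ending in _x_at or _s_at, a 2-fold minimum, an adjusted p under 0.01, a fit on only the groups compared, the replicate number as a block, and leaving out each array in turn. Added after seeing the data were fits without the 3 control arrays with pancreatic transcripts, with the pancreas, the liver and lung, or the erythroid list means as covariates, with the first principal component of the residuals as a covariate, and without the 2 wild-type control arrays with low Xist. The list tests were not rerun with the trend and robust prior, the weights, the sets ending in _x_at or _s_at left out, only the groups compared, the 2-fold minimum or the stricter threshold. A list adjusted for its own mean was not tested. Array files before RMA were not used here, so the authors' background adjustment and summary could not be varied.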

Results

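The series asks how Dusp1 controls the response to LPS. Dusp1 encodes a phosphatase that switches off MAP kinases. Spleen RNA was measured in 12 mice, in 4 groups of 3: wild-type control, wild-type 6 h after LPS, and the same treatments in mice labelled Dusp1 knockout. Groups and arrays are written here as wild-type or knockout, control or LPS, with the replicate number of the labels. Within a group, correlations between arrays across all probe sets ran from 0.938 to 0.961 in wild-type controls and from 0.909 to 0.950 in knockout controls. After LPS they ran from 0.963 to 0.986 in wild-type and from 0.965 to 0.989 in knockout arrays. These are across probe sets, which are not independent replicates. The median SD within a group on the log2 scale was 0.30 for wild-type controls, 0.24 for wild-type LPS, 0.35 for knockout controls and 0.22 for knockout LPS. The first principal component carried 41.9% of the variance and parted the LPS arrays from the controls, and the next carried 14.9%.

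Dusp1 itself was not lower in the arrays labelled knockout. Its intensity was 479, 1354 and 627 in wild-type controls and 677, 1528 and 1443 in knockout controls. After LPS it was 2248, 2142 and 2116 in wild-type and 4963, 2948 and 4996 in knockout arrays, above every wild-type array in 3 of 3. That difference after LPS (0.95 ± 0.41) did not pass (limma adjusted p = 0.528, and 0.0213 to 0.945 over 27 alternatives, of which array quality weights alone gave a call), nor did the one in controls (0.63 ± 0.41, adjusted p = 1.00). Dusp1 rose with LPS in wild-type (1.55 ± 0.41, adjusted p = 0.0487) and in knockout spleen (1.87 ± 0.41, adjusted p = 0.0132). The wild-type call was lost without any 1 of wild-type control 1 or 3, wild-type LPS 1, 2 or 3, knockout control 3, or knockout LPS 1 or 3, where its adjusted p reached 0.161. The knockout call was lost without knockout LPS 1 or 3, with an adjusted p of up to 0.0596. Where the probe set lies relative to the altered part of the gene is not stated, so its signal does not check the labels, and every direction between genotypes rests on them.

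Transcripts of tissues beside the spleen differed between arrays within groups. The pancreas list (digestive enzymes such as the trypsinogen Prss2) had a mean log2 intensity of 11.64 in wild-type control 1, 10.42 in knockout control 1 and 7.84 in knockout control 3, and from 4.12 to 5.03 in the other 9 arrays. Prss2 read 8116, 3981 and 503 in those 3 arrays. The liver list averaged from 4.32 in knockout control 1 to 9.39 in knockout control 2, with albumin (Alb) from 26 to 5986. Among LPS arrays its mean was 6.50, 9.13 and 8.14 in knockout and 6.44, 8.15 and 6.01 in wild-type mice. Lung transcripts lay mostly in arrays labelled knockout: the surfactant gene Sftpc read 966 and 895 in knockout controls 2 and 3 and 735 and 311 in knockout LPS 1 and 3, against 15 to 94 in the other 8. The lung list averaged 6.58, 4.74 and 6.01 in knockout LPS arrays and 4.79, 4.63 and 4.49 in wild-type LPS arrays. Red cell precursor transcripts were highest in knockout control 1 (mean 10.45) and wild-type control 2 (9.26), against 5.79 to 7.74 elsewhere. Xist, expressed from the inactive X chromosome, read 35 and 47 in wild-type controls 2 and 3 and 1101 to 3949 in the other arrays. The Y-linked Eif2s3y read 316 and 53 in those arrays and 7 to 10 elsewhere. Uty (21 and 11 against 9 to 11) and Kdm5d (16 and 11 against 10 to 13) stood out in wild-type control 2 alone. So wild-type control 2 and, by Xist and Eif2s3y only, 3 had the pattern of male tissue and the remaining 10 that of female tissue. Both are wild-type controls, so sex is partly mixed with LPS or genotype in every contrast that uses those controls.

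**Figure D1:**
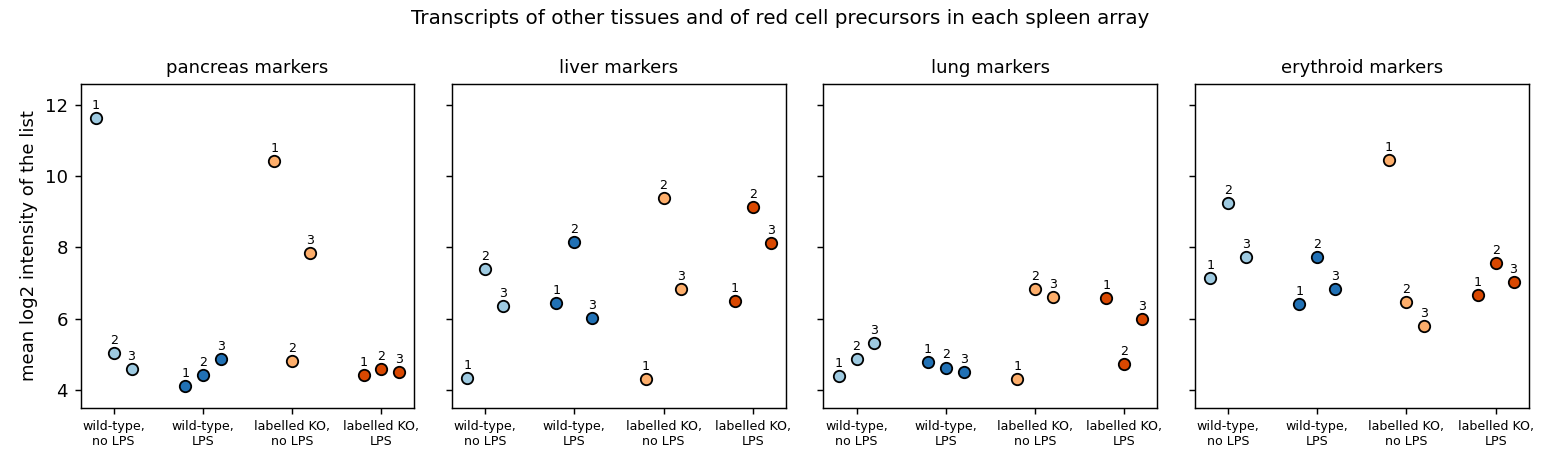
Mean log2 intensity (vertical axis) of marker lists of other tissues and of red cell precursors in each of the 12 arrays, with 1 point per array, by group (horizontal axis). The pancreas list stood at 11.64, 10.42 and 7.84 in 3 control arrays and between 4.12 and 5.03 in the other 9.

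In wild-type spleen, which asks what LPS does to the intact response, genes of acute inflammation rose. The collagenase gene Mmp13 rose from a mean intensity of 10.9, near background, to 1466 (7.07 ± 0.35 on the log2 scale, adjusted p = 6.32e-06, higher in 3 of 3 mice), and the interferon-induced chemokine gene Cxcl11 from 16.6 to 1868 (6.81 ± 0.36). With controls this dim, as also for Acod1, Cxcl2, Il6, Ccl3, Ifng, Ptgs2 and Il10 (up to 25.1), the size and rank of rises depend on the floor of the arrays. Acod1 (6.22 ± 0.30), whose enzyme makes itaconate, the acute phase gene Saa3 (6.06 ± 0.41), the neutrophil-attracting Cxcl2 (5.30 ± 0.45) and Cxcl1 (5.06 ± 0.63) and the cytotoxic granzyme gene Gzmb (5.24 ± 0.36) followed. Il6 (4.99 ± 0.61), the protease inhibitor gene Timp1 (4.85 ± 0.34) and Ccl3 (4.79 ± 0.40) completed the 10 largest. The largest fall was that of Slc40a1, the iron exporter of red pulp macrophages, from 2499 to 30.2 (-6.37 ± 0.62, adjusted p = 0.000268). Among single genes, falls included Cavin2 (-3.56 ± 0.25) and Cav1 (-3.07 ± 0.32), which coat caveolae, Stab2 (-3.08 ± 0.28), a scavenger receptor of sinus endothelium, and Tcf21 (-3.47 ± 0.28), a transcription factor of splenic mesenchyme, while the endothelial list was not called. Hpgd (-3.06 ± 0.36), which breaks down prostaglandins, and Abcg3 (-3.54 ± 0.55), Efhd1 (-3.48 ± 0.44), Slc45a3 (-3.24 ± 0.42) and Kazald1 (-3.22 ± 0.37) were the other large falls. Of the genes named in advance, Ccl2 (4.69 ± 0.41), Ifng (4.28 ± 0.36), Ccl4 (3.87 ± 0.30), Ptgs2 (3.46 ± 0.37), Socs3 (3.25 ± 0.47), Tnf (2.37 ± 0.29) and Il10 (2.36 ± 0.23) rose, while Il1b (1.85 ± 0.58, adjusted p = 0.0906) and Nos2 (0.13 ± 0.24, adjusted p = 0.865) did not pass.

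In all 1002 genes (1491 probe sets) passed in wild-type spleen, 487 higher and 515 lower, of which 449 and 419 changed at least 2-fold. The groups did not overlap for 3096 genes, or 24.98%, where chance gives 10%. Leaving out 1 array moved the count to 608 without wild-type control 1, 544 without wild-type control 2, 490 without wild-type LPS 2 and 389 without wild-type LPS 3. Of all calls 48.6% were higher, against 59.5% when every array was shifted to 1 median, a shift of 0.12 in the median of all probe sets, and 54.2% after cyclic loess, and no called gene changed sign in either.

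By camera at the preset correlation, 14 of the 41 lists were higher and 5 lower than other genes in wild-type spleen after LPS, and 13 lists passed in fry. Members not counted as risen or fallen did not pass. Of the 34 interferon-stimulated genes, 24 rose and 0 fell (30 and 0 adjusted over the list alone), among them Oasl1 (4.48 ± 0.38), Mx1 (3.70 ± 0.64), Ifit2 (3.69 ± 0.67) and Usp18 (3.65 ± 0.42). Their median was 2.21 (adjusted p = 6.02e-28, and held at 0.0479 with an estimated correlation). Of the 26 chemokines, 16 rose and 1 fell (17 and 2 adjusted over the list alone). Their median was 2.97 (adjusted p = 5.48e-18, and held at 0.0479 with an estimated correlation). Of the 22 anti-inflammatory and feedback regulators, 13 rose and 0 fell (15 and 0 adjusted over the list alone), among them Il1rn (4.78 ± 0.35), Socs1 (4.02 ± 0.46) and Atf3 (3.71 ± 0.42). Their median was 1.56 (adjusted p = 5.31e-14, and 0.125 with an estimated correlation). Acute phase genes and STAT3 targets had 8 rises and 0 falls in 24 (14 and 0 adjusted over the list alone), among them Lcn2 (4.28 ± 0.55). Their median was 1.99 (adjusted p = 2.57e-13, and 0.159 with an estimated correlation). Of the 23 proinflammatory cytokines, 9 rose and 0 fell (11 and 0 adjusted over the list alone), among them Csf3 (4.61 ± 0.31) and Il1a (2.82 ± 0.45). Their median was 1.21 (adjusted p = 6.87e-10, and 0.106 with an estimated correlation). The NF-kB pathway had 7 rises and 0 falls in 21 (11 and 0 adjusted over the list alone), among them Cd40 (2.69 ± 0.41), Tnfaip3 (2.57 ± 0.44) and Nfkbiz (2.38 ± 0.33). Their median was 1.13 (adjusted p = 2.60e-09, and 0.234 with an estimated correlation). Prostaglandin, nitric oxide and macrophage effector enzymes had 6 rises and 2 falls in 19 (8 and 2 adjusted over the list alone), among them Sod2 (2.48 ± 0.13) and Ptges (2.32 ± 0.34). Their median was 1.17 (adjusted p = 8.00e-06, and 0.0529 with an estimated correlation). Matrix remodelling genes had 6 rises and 2 falls in 20 (7 and 2 adjusted over the list alone), among them Adamts4 (3.88 ± 0.33) and Mmp3 (3.81 ± 0.41). Their median was 0.62 (adjusted p = 0.000185, and 0.363 with an estimated correlation). Coagulation and endothelial activation genes had 7 rises and 2 falls in 24 (11 and 2 adjusted over the list alone), among them Procr (2.69 ± 0.49) and Edn1 (2.14 ± 0.32). Their median was 0.86 (adjusted p = 0.000330, and 0.403 with an estimated correlation). MHC class I and immunoproteasome genes had 2 rises and 0 falls in 13 (6 and 1 adjusted over the list alone). Their median was 0.61 (adjusted p = 0.00772, and 0.564 with an estimated correlation). Apoptosis genes had 0 rises and 0 falls in 19 (0 and 0 adjusted over the list alone). Their median was 0.51 (adjusted p = 0.0229, and 0.564 with an estimated correlation). AP-1 and immediate-early genes had 5 rises and 2 falls in 23 (6 and 2 adjusted over the list alone), among them Ier3 (2.88 ± 0.49) and Maff (2.60 ± 0.35). Their median was 0.39 (adjusted p = 0.0231, and 0.726 with an estimated correlation). Glycolysis and hypoxia genes had 4 rises and 0 falls in 22 (7 and 3 adjusted over the list alone), among them Hk2 (2.40 ± 0.33) and Adm (2.33 ± 0.40). Their median was 0.32 (adjusted p = 0.0254, and 0.634 with an estimated correlation). The antioxidant and metal list had 5 rises and 2 falls in 20 (7 and 3 adjusted over the list alone), among them Mt2 (4.07 ± 0.51) and Mt1 (3.28 ± 0.29). Their median was 0.062 (adjusted p = 0.0320, and 0.585 with an estimated correlation).

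Among the 5 lower lists were those of resident cells. Monocyte and macrophage markers had 2 rises and 7 falls in 27 (3 and 13 adjusted over the list alone), among them Cd163 (-2.72 ± 0.41, to 12.9, near background) and Cd5l (-2.72 ± 0.23), beside a rise of Cd14 (2.61 ± 0.23). Their median was -0.57 (adjusted p = 0.000394, and 0.208 with an estimated correlation). Stromal and smooth muscle markers had 0 rises and 3 falls in 23 (0 and 6 adjusted over the list alone), among them Tlx1 (-1.47 ± 0.29), a transcription factor of spleen development (lost without wild-type LPS 2 or 3, adjusted p up to 0.0614). Their median was -0.70 (adjusted p = 0.000162, and 0.403 with an estimated correlation). Of the 18 T cell markers, 1 rose and 2 fell (1 and 7 adjusted over the list alone). Their median was -0.78 (adjusted p = 0.00305, and 0.726 with an estimated correlation). Of the 15 B cell markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone). Their median was -0.84 (adjusted p = 0.00941, and 0.585 with an estimated correlation). Pancreas markers had 0 rises and 0 falls in 17 (0 and 0 adjusted over the list alone) and were high in wild-type control 1 alone of this comparison's arrays. Their median was -2.83 (adjusted p = 0.0201, and 0.726 with an estimated correlation). The calls of 6 lists were lost without 1 array. They were pancreas (adjusted p up to 0.938), AP-1 (0.132) and glycolysis (0.0715), each without wild-type control 1 or wild-type LPS 1, and MHC class I (0.0669) without wild-type LPS 1. Apoptosis (0.234) was lost without wild-type control 3 or wild-type LPS 1, and antioxidant (0.145) without wild-type control 1 or 3 or wild-type LPS 1.

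The other 22 lists were not called in wild-type spleen. With members risen and fallen, those adjusted over the list alone, and the adjusted camera p, these included DUSP phosphatases (2 and 1 of 16, 4 and 2 over the list alone, adjusted p = 0.631), MAP kinases (4 and 2 of 23, 5 and 4 over the list alone, adjusted p = 0.957), Toll-like receptors (2 and 0 of 19, 2 and 0 over the list alone, adjusted p = 0.190) and complement (1 and 1 of 15, 4 and 2 over the list alone, adjusted p = 0.705). Antigen presentation, growth and metabolism gave MHC class II (0 and 0 of 11, 0 and 0 over the list alone, adjusted p = 0.190), cell cycle (0 and 0 of 26, 0 and 0 over the list alone, adjusted p = 0.0649), ribosomal proteins (0 and 0 of 18, 0 and 0 over the list alone, adjusted p = 0.705), oxidative phosphorylation (1 and 0 of 26, 2 and 0 over the list alone, adjusted p = 0.308) and cholesterol and fatty acid synthesis (0 and 1 of 17, 0 and 1 over the list alone, adjusted p = 0.161). Stress lists gave glucocorticoid response (5 and 1 of 18, 6 and 2 over the list alone, adjusted p = 0.0774) and heat shock and unfolded protein response (3 and 2 of 21, 3 and 4 over the list alone, adjusted p = 0.705). Markers of blood cells gave plasma cells (1 and 0 of 7, 2 and 1 over the list alone, adjusted p = 0.697), NK cells (1 and 1 of 14, 3 and 2 over the list alone, adjusted p = 0.344), neutrophils (3 and 0 of 18, 3 and 0 over the list alone, adjusted p = 0.267), dendritic cells (4 and 2 of 14, 6 and 2 over the list alone, adjusted p = 0.0735), erythroid cells (0 and 0 of 22, 0 and 0 over the list alone, adjusted p = 0.0979), platelets (1 and 0 of 13, 1 and 0 over the list alone, adjusted p = 0.695) and mast cells (0 and 0 of 12, 0 and 0 over the list alone, adjusted p = 0.885). Tissue markers gave endothelium (0 and 2 of 19, 1 and 3 over the list alone, adjusted p = 0.171), adipocytes (0 and 1 of 14, 0 and 1 over the list alone, adjusted p = 0.928), mesothelium and epithelium (0 and 0 of 11, 0 and 0 over the list alone, adjusted p = 0.985) and sex-linked genes (0 and 0 of 4, 0 and 0 over the list alone, adjusted p = 0.505). Median, mean and test differed in sign for 5 of these lists (complement, plasma cell, neutrophil, mast cell and adipocyte). The medians of 6 changed sign under a scaling: complement, ribosomal, plasma cell, neutrophil, mast cell and mesothelial.

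In spleen labelled knockout, LPS raised many of the same genes. Mmp13 rose from 10.5 to 3090 (8.21 ± 0.35, adjusted p = 1.84e-06) and Il6, a cytokine that drives the acute phase, from 20.4 to 2675 (7.04 ± 0.61, adjusted p = 8.11e-05). The chemokine genes Cxcl2 (6.81 ± 0.45), Cxcl1 (6.80 ± 0.63), Cxcl11 (6.65 ± 0.36), Ccl3 (6.60 ± 0.40), Ccl4 (6.24 ± 0.30), Cxcl5 (5.93 ± 0.74) and Ccl12 (5.88 ± 0.23) and the interferon-induced Mx1 (5.87 ± 0.64) made up the rest of the 10 largest, each higher in 3 of 3 mice. Of these 10, Mmp13, Il6, Cxcl2, Cxcl11, Ccl3, Cxcl5 and Ccl12 started from control means of 10.5 to 27.1, so the floor bears on their size and rank. Falls were led by Cavin2 (-4.19 ± 0.25) and Tcf21 (-4.12 ± 0.28) and by Pcmtd2 (-3.80 ± 0.62) and Abcg3 (-3.61 ± 0.55). They took in Mxd4 (-3.58 ± 0.43), a repressor in the Myc network, Add3 (-3.33 ± 0.42), which builds the membrane skeleton, Slc40a1 (-3.29 ± 0.62) and Rasgrp2 (-3.07 ± 0.46), an activator of Rap in platelets. Stbd1 (-3.22 ± 0.75), which binds glycogen, was lost without knockout control 3 or knockout LPS 2 (adjusted p up to 0.0665). Tpcn1 (-3.06 ± 0.43), an endolysosomal channel, had another 2 probe sets, of which 1 had the same sign. Ccl2 (5.67 ± 0.41), Ptgs2 (5.29 ± 0.37), Socs3 (4.21 ± 0.47), Il10 (4.05 ± 0.23), Ifng (3.46 ± 0.36) and Il1b (2.83 ± 0.58) rose too, Ptgs2, Il10 and Ifng from that floor (up to 16.3). Tnf (0.67 ± 0.29, adjusted p = 0.177) and Nos2 (0.30 ± 0.24, adjusted p = 0.523) did not pass.

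Calls in knockout spleen numbered 1889 genes (2869 probe sets), 686 higher and 1203 lower, with 588 and 952 of at least 2-fold. Groups did not overlap for 3576 genes, or 28.9%, where chance gives 10%. Without knockout LPS 1 the count was 988 and without knockout LPS 3 it was 1155. The share of calls that were higher, 36.3%, became 47.2% after cyclic loess and 55.1% with every array shifted to 1 median, which moved the median of all probe sets by 0.22, and no called gene changed sign in either.

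Camera called 19 lists in knockout spleen, 16 higher and 3 lower, and fry 18. Of the 34 interferon-stimulated genes, 28 rose and 0 fell (32 and 0 adjusted over the list alone), among them Ifit2 (5.21 ± 0.67), Oasl1 (4.77 ± 0.38) and Zbp1 (4.07 ± 0.31). Their median was 2.87 (adjusted p = 2.70e-28, and held at 0.0444 with an estimated correlation). Of the 26 chemokines, 16 rose and 1 fell (17 and 1 adjusted over the list alone). Their median was 2.53 (adjusted p = 1.70e-18, and held at 0.0444 with an estimated correlation). Of the 22 anti-inflammatory and feedback regulators, 15 rose and 0 fell (20 and 0 adjusted over the list alone), among them Il1rn (5.41 ± 0.35) and Nfkbiz (4.24 ± 0.33). Their median was 1.93 (adjusted p = 9.45e-18, and 0.0691 with an estimated correlation). Acute phase genes and STAT3 targets had 12 rises and 0 falls in 24 (17 and 0 adjusted over the list alone), among them Saa3 (4.63 ± 0.41) and Fgl2 (3.62 ± 0.64). Their median was 2.19 (adjusted p = 9.28e-15, and 0.107 with an estimated correlation). Of the 23 proinflammatory cytokines, 12 rose and 0 fell (14 and 1 adjusted over the list alone), among them Csf3 (5.33 ± 0.31) and Lif (2.92 ± 0.20). Their median was 1.29 (adjusted p = 1.79e-11, and 0.0691 with an estimated correlation). NF-kB pathway members had 10 rises and 0 falls in 21 (13 and 0 adjusted over the list alone), among them Map3k8 (3.54 ± 0.36), Tnfaip3 (3.26 ± 0.44) and Rel (2.60 ± 0.35). Their median was 1.31 (adjusted p = 1.02e-10, and 0.158 with an estimated correlation). Genes of coagulation and endothelial activation had 13 rises and 0 falls in 24 (14 and 0 adjusted over the list alone), among them Adamts4 (4.50 ± 0.33), Edn1 (4.48 ± 0.32) and Plat (3.87 ± 0.31). Their median was 1.78 (adjusted p = 3.74e-10, and 0.107 with an estimated correlation). Extracellular matrix remodelling genes had 11 rises and 1 fall in 20 (12 and 3 adjusted over the list alone), among them Timp1 (4.67 ± 0.34) and Mmp3 (3.39 ± 0.41). Their median was 1.22 (adjusted p = 1.04e-06, and 0.158 with an estimated correlation). Enzymes of prostaglandin, nitric oxide and macrophage effectors had 8 rises and 1 fall in 19 (11 and 1 adjusted over the list alone), among them Acod1 (5.20 ± 0.30), Cybb (2.12 ± 0.35) and Slc7a2 (2.11 ± 0.43). Their median was 1.24 (adjusted p = 2.86e-06, and held at 0.0444 with an estimated correlation). Immediate-early and AP-1 genes had 9 rises and 1 fall in 23 (9 and 2 adjusted over the list alone), among them Atf3 (3.83 ± 0.42), Maff (3.01 ± 0.35), Ier3 (2.77 ± 0.49) and Jun (2.63 ± 0.58). Their median was 0.75 (adjusted p = 3.27e-06, and 0.438 with an estimated correlation). Antioxidant and metal genes had 6 rises and 1 fall in 20 (6 and 1 adjusted over the list alone), among them Mt2 (3.78 ± 0.51), Mt1 (3.41 ± 0.29) and Slc7a11 (2.07 ± 0.24). Their median was 0.45 (adjusted p = 0.000179, and 0.244 with an estimated correlation). Genes of apoptosis had 7 rises and 1 fall in 19 (7 and 1 adjusted over the list alone), among them Pmaip1 (2.28 ± 0.46) against a fall of Casp9 (-2.44 ± 0.32). Their median was 0.70 (adjusted p = 0.00198, and 0.336 with an estimated correlation). Glucocorticoid-responsive genes had 5 rises and 1 fall in 18 (5 and 1 adjusted over the list alone), among them Lcn2 (3.43 ± 0.55) and Cdkn1a (3.27 ± 0.29). Their median was 0.48 (adjusted p = 0.00326, and 0.531 with an estimated correlation). Genes of glycolysis and hypoxia had 8 rises and 1 fall in 22 (10 and 3 adjusted over the list alone), among them Adm (2.88 ± 0.40), Hk2 (2.60 ± 0.33), Pfkfb3 (2.36 ± 0.48) and Ndrg1 (2.26 ± 0.27). Their median was 0.52 (adjusted p = 0.00453, and 0.531 with an estimated correlation). The MHC class I and immunoproteasome list had 2 rises and 0 falls in 13 (2 and 0 adjusted over the list alone). Their median was 0.34 (adjusted p = 0.0230, and 0.581 with an estimated correlation). Toll-like receptor genes had 4 rises and 1 fall in 19 (4 and 2 adjusted over the list alone), among them Cd14 (3.66 ± 0.23), Myd88 (1.48 ± 0.24) and Tlr2 (1.37 ± 0.23). Their median was 0.23 (adjusted p = 0.0379, and 0.581 with an estimated correlation).

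The lower lists were cell cycle, stroma and pancreas, of which cell cycle genes had 0 rises and 3 falls in 26 (0 and 3 adjusted over the list alone). Their median was -1.27 (adjusted p = 0.000394, and 0.702 with an estimated correlation). Stromal markers had 0 rises and 4 falls in 23 (0 and 4 adjusted over the list alone), among them Pdgfrb (-2.64 ± 0.49) and Tlx1 (-2.48 ± 0.29). Their median was -0.51 (adjusted p = 0.0380, and 0.702 with an estimated correlation). Markers of pancreas had 0 rises and 0 falls in 17 (0 and 0 adjusted over the list alone) and were high in knockout controls 1 and 3. Their median was -3.60 (adjusted p = 0.0458, and 0.825 with an estimated correlation). The call was lost without knockout control 1 for MHC class I, cell cycle and Toll-like receptors (adjusted p = 0.234 each), and for the last also without knockout LPS 3. The cell cycle mean was highest, as was the red cell mean, in knockout control 1 (9.61) and wild-type control 2 (8.54), against 7.43 to 7.70 in the other controls. With the red cell mean as a covariate the list was still called (mean -0.93). Stromal markers lost it without knockout control 2 or 3 or knockout LPS 3 (up to 0.134). Pancreas lost it without knockout control 1 or 3, any knockout LPS array, or wild-type LPS 1 or 3 (up to 0.649). Outside the called lists Fcer2a (-2.60 ± 0.47) and Cd79b (-2.14 ± 0.40) of B cells and Cd5 (-2.87 ± 0.50) of T cells fell, while Gzmb (5.43 ± 0.36) and Dusp16 (2.76 ± 0.31) and Dusp2 (2.34 ± 0.51), phosphatases of the DUSP family, rose. Median, mean and test differed in sign for 13 lists, none of them called, and the medians of 10 uncalled lists changed sign under a scaling, DUSP phosphatases, MAP kinases, ribosomal proteins and oxidative phosphorylation among them.

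Set side by side, the LPS responses of the genotypes shared 364 genes called higher in both (26.96 by independence) and 373 called lower in both (49.99), and 0 were called in opposite directions. Calls in wild-type alone numbered 123 higher and 142 lower, and calls in knockout alone 322 higher and 830 lower, which by itself does not show a different response (the interaction was tested separately). Across the 12393 genes the responses correlated with Pearson r = 0.801 and Spearman rho = 0.7004, and across the 2154 genes called in either with 0.880 and 0.817. Genes are not independent replicates. Averaged over the genotypes, 2833 genes (4480 probe sets) responded, 1056 higher and 1777 lower. The 37.3% of these that were higher became 46.9% after cyclic loess and 54.4% with arrays shifted to 1 median, a shift of 0.17. The averaged response called 21 lists, 15 higher and 6 lower, of which chemokines, interferon-stimulated genes and macrophage effector enzymes held with an estimated correlation (adjusted p = 0.0455). For the other 18 the adjusted p with an estimated correlation reached 0.760, and fry called 21. Calls lost without 1 array were B cells without knockout control 3 (0.0801), pancreas without knockout control 1 (0.116), macrophages without knockout control 1 or 3 or wild-type control 2 (up to 0.127), and glucocorticoid response without knockout control 1, wild-type control 1 or wild-type LPS 1 (up to 0.0828). In this response Slc40a1 (-4.83 ± 0.44) fell and Acod1 (5.71 ± 0.22) and Saa3 (5.35 ± 0.29) rose.

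**Figure D2:**
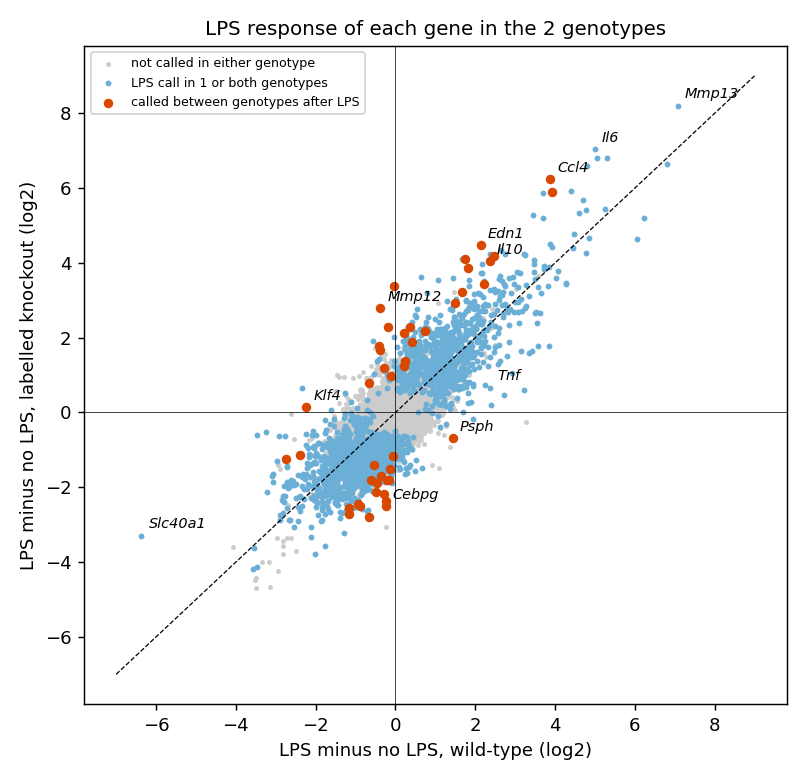
LPS response of each gene as a log2 difference between groups of 3 mice, in wild-type (horizontal axis) and labelled knockout spleen (vertical axis), with 1 point per gene, genes called in 1 or both genotypes in blue and the 45 called between genotypes after LPS in orange. The 364 genes called higher and the 373 called lower in both lay along the diagonal, with 0 called in opposite directions.

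**Figure D3:**
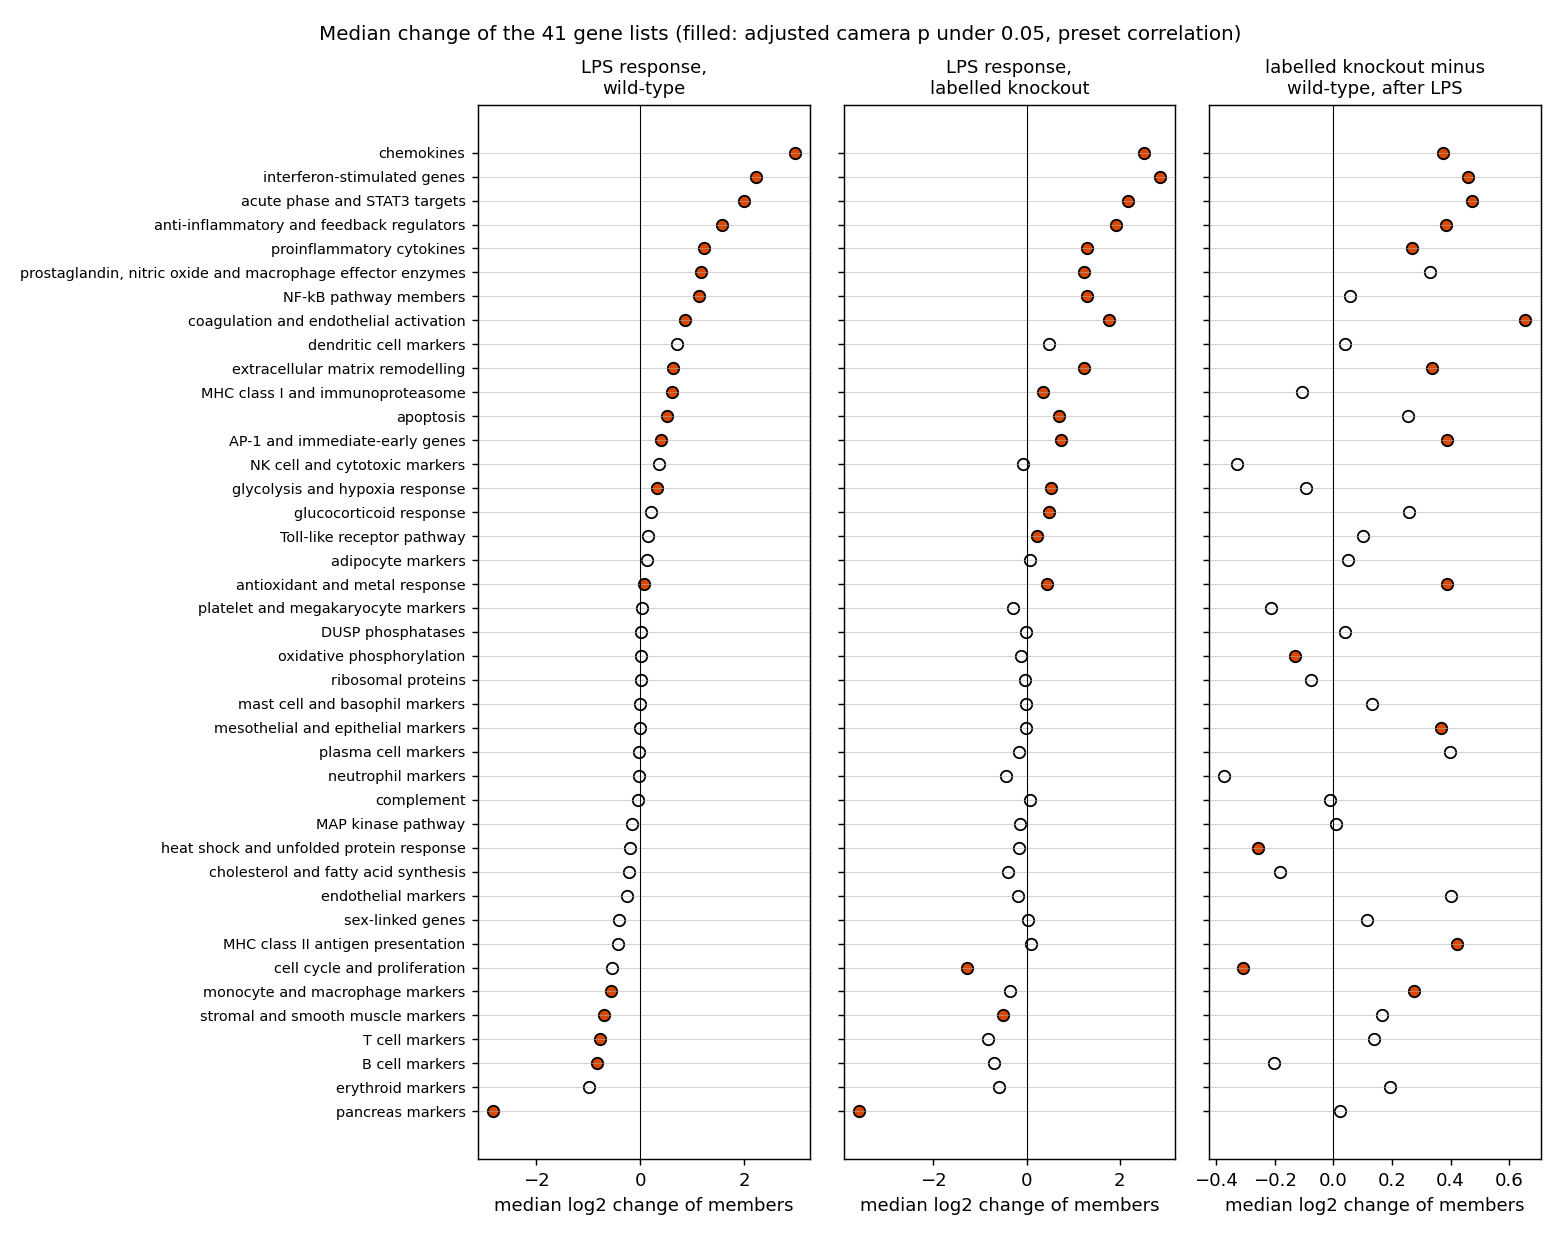
Median log2 change of the members of each of the 41 lists (horizontal axis) in the LPS response of wild-type spleen, in that of labelled knockout spleen and between genotypes after LPS, with filled points for an adjusted camera p under 0.05 at the preset correlation. Chemokines had medians of 2.97, 2.53 and 0.38 and interferon-stimulated genes of 2.21, 2.87 and 0.46 in the 3 comparisons.

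Without LPS, the comparison of knockout with wild-type spleen called 0 genes by limma, and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 176 genes, fewer than the 619.7 that chance gives. With a trend and robust prior, cyclic loess, a median shift or array weights the call count was also 0, with 168, 212, 145 and 86 genes at that p. Leaving out wild-type control 1 gave 1 gene. Without the 3 control arrays with pancreatic transcripts, which leaves 1 knockout control, the count was 155 (1877 at that p), and without the 2 wild-type controls with low Xist it was 3 (562). Groups did not overlap for 308 genes, or 2.49%, where chance gives 10%. The genes named in advance included Tnf (0.32 ± 0.29), Il6 (0.69 ± 0.61), Il10 (0.038 ± 0.23), Il1b (-0.33 ± 0.58), Ccl2 (0.0021 ± 0.41), Ccl3 (0.35 ± 0.40), Ccl4 (0.12 ± 0.30) and Cxcl2 (0.38 ± 0.45), none of which passed, and neither did Ifng (0.33 ± 0.36), Nos2 (0.16 ± 0.24), Ptgs2 (-0.038 ± 0.37) and Socs3 (0.20 ± 0.47). The control arrays held the pancreatic and the highest red cell signal given above, and lung means of 4.29, 6.84 and 6.62 in knockout against 4.39, 4.86 and 5.32 in wild-type arrays. Wild-type controls 2 and 3 alone had the male pattern of Xist, so sex is partly mixed with genotype here and in the interaction.

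Camera called 12 lists in controls at the preset correlation, 11 lower and 1 higher in knockout spleen, and 0 held with an estimated correlation or in fry. Lower were the NF-kB pathway (median -0.19, adjusted p = 0.000288, and 0.621 with an estimated correlation), B cells (median -0.14, adjusted p = 0.00220, and 0.621 with an estimated correlation), monocytes and macrophages (median -0.11, adjusted p = 0.00567, and 0.621 with an estimated correlation), MHC class II (median -0.14, adjusted p = 0.0121, and 0.621 with an estimated correlation) and anti-inflammatory regulators (median -0.10, adjusted p = 0.0121, and 0.776 with an estimated correlation). So was heat shock (median -0.092, adjusted p = 0.0126, and 0.385 with an estimated correlation). In that order of values, erythroid markers (-0.44, 0.0126 and 0.849), glycolysis (-0.062, 0.0135 and 0.776) and NK cells (-0.13, 0.0195 and 0.621) were lower too. So were sex-linked genes (-0.40, 0.0484 and 0.621), whose mean of 0.11 had the other sign. The male pattern of wild-type controls 2 and 3 enters this list directly, so its call does not show a genotype difference. The last lower list was ribosomal proteins (median -0.050, adjusted p = 0.0195, and 0.621 with an estimated correlation), whose median became 0.058 after cyclic loess. Higher was mesothelial and epithelial markers (median 0.34, adjusted p = 0.0126, and 0.621 with an estimated correlation), beside the lung transcripts given above. No member passed over all probe sets, and adjusted over the list alone 1 sex-linked gene was higher and 1 lower and 1 NF-kB gene was lower. The number of lists was 19 without wild-type control 1, 6 without wild-type control 2, 3 without wild-type control 3 and 20 without knockout control 2, and each of the 12 calls was lost without at least 1 control array. The mean of erythroid markers turned to 0.13 without wild-type control 2, 0.074 without knockout control 2 and 0.42 without knockout control 3. Without knockout control 1, the array with the highest red cell mean, those of the NF-kB and anti-inflammatory lists turned to 0.10 and 0.19. With liver and lung covariates erythroid markers were called the other way (0.82, adjusted p = 0.000612), and without the 2 wild-type controls with low Xist their mean turned to 0.44 and that of the anti-inflammatory list to 0.17. Median, mean and test differed in sign for 15 lists. Under a scaling the medians of 10 changed sign, of which ribosomal proteins alone was called.

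After LPS, the comparison the series was built for, 27 genes were higher and 18 lower in spleen labelled knockout. Mmp12, the macrophage elastase gene, was higher (3.13 ± 0.54, adjusted p = 0.0442), at 176, 61 and 342 against 16, 17 and 20 in wild-type LPS arrays, a background level that sets the size of its difference. Ccl4, a chemokine gene for monocytes and T cells, was 5.63-fold higher (2.49 ± 0.30, adjusted p = 0.0118). Edn1 (2.42 ± 0.32, adjusted p = 0.0136) encodes a vasoconstrictor peptide, Rcan1 (2.31 ± 0.27, adjusted p = 0.0115) a calcineurin inhibitor and Plat (2.22 ± 0.31, adjusted p = 0.0201) the tissue plasminogen activator. Ccl12 (2.02 ± 0.23), another monocyte chemokine, Rin2 (1.96 ± 0.21), which acts on endosomal GTPases, the matrix protein gene Ccn1 (1.95 ± 0.32), the cadherin gene Cdh17 (2.09 ± 0.36) and Gm13889 (1.95 ± 0.30) completed the 10 largest. Of the genes named in advance, Ccl4 and the anti-inflammatory cytokine gene Il10 (3.31-fold, 1.73 ± 0.23, adjusted p = 0.0173) passed. Not passed were Il6 (2.74 ± 0.61, adjusted p = 0.112), Ccl3 (2.16 ± 0.40, 0.0611), Cxcl2 (1.90 ± 0.45, 0.144), Ptgs2 (1.79 ± 0.37, 0.0884) and Tnf (-1.38 ± 0.29, 0.0885), the last with a lower mean in knockout spleen. Nor did Socs3 (1.15 ± 0.47, 0.486), Ccl2 (0.98 ± 0.41, 0.504), Il1b (0.64 ± 0.58, 0.892), Nos2 (0.33 ± 0.24, 0.839) or Ifng (-0.49 ± 0.36, 0.832) pass.

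Lower in knockout spleen after LPS were Cebpg (-2.55 ± 0.33, adjusted p = 0.0131), a partner of C/EBP factors, and Psph (-2.16 ± 0.37, 0.0422), which makes serine. The ubiquitin ligase genes Tmem129 (-1.96 ± 0.32) and Rnf181 (-1.57 ± 0.27), the mitochondrial ribosome gene Mrpl49 (-1.73 ± 0.28), the Mediator subunit gene Med20 (-1.69 ± 0.22), 6030458C11Rik (-1.87 ± 0.20) and Ngrn (-1.65 ± 0.28) and Crebzf (-1.75 ± 0.27), a stress-response factor, were lower as well. Pigc (-1.53 ± 0.24), an enzyme of membrane anchors, had another probe set at 0.26, and of the other 2 probe sets of Crebzf 1 had the same sign. Adjusted p over 27 alternatives ran from 0.000665 to 0.0536 for Ccl4, 0.000936 to 0.0712 for Il10, 0.000655 to 0.0988 for Edn1, 0.000928 to 0.194 for Mmp12 and 0.00157 to 0.0726 for Cebpg. Leaving out 1 array at a time, 6030458C11Rik alone of the 24 named calls passed in all 12 fits. Ccl12 and Rcan1 were lost without wild-type LPS 2 or 3 and Rin2 without wild-type LPS 2 (adjusted p = 0.0589). Ccl4 was lost without knockout LPS 2 or 3 or wild-type LPS 3 (up to 0.0536), and Edn1 without knockout LPS 2 or 3 or wild-type LPS 2 or 3 (up to 0.0988). Il10 was lost without any 1 knockout LPS array or wild-type LPS 2 or 3 (up to 0.0712), and Cebpg without knockout LPS 3 or wild-type LPS 2 or 3 (up to 0.0726). Med20 was lost without the same arrays as Cebpg (up to 0.0763), Lif without knockout LPS 1 or 3 or wild-type LPS 2 (up to 0.0742) and Ptx3 without the same arrays as Il10 (up to 0.108). Plat was lost without knockout LPS 1 or 2 or wild-type LPS 2 or 3 (up to 0.108). The other 12 named genes passed in 2 to 5 of the 12 fits, were each lost without wild-type control 2, wild-type LPS 2 or wild-type LPS 3, and reached an adjusted p of up to 0.217 for Cdh17. None of the 24 reversed.

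In all 45 genes (72 probe sets) were called after LPS, 27 higher and 18 lower, and 1269 genes had an unadjusted p under 0.05 where chance gives 619.7. Groups did not overlap for 2272 genes, or 18.3%, where chance gives 10%. The count hung on single arrays: it was 3 without wild-type LPS 2, 5 without wild-type LPS 3, 7 without knockout LPS 3, 12 without knockout LPS 2, 13 without knockout LPS 1, 18 without wild-type control 2, 24 without knockout control 3, 28 without wild-type LPS 1 and 68 without knockout control 1. Other settings moved it further, to 0 with a fit on only the 2 groups compared (1861 genes at an unadjusted p under 0.05), 1280 with array quality weights, 171 with the first residual component as a covariate, 12 with a replicate block, 79 without the 3 control arrays with pancreatic transcripts, 27 without dim probe sets and 22 without the 2 wild-type controls with low Xist. In wild-type spleen, whose LPS arrays also enter this comparison, 10 of the 27 higher genes rose with LPS, Ccl4, Ccl12, Edn1, Il10, Lif, Plat and Ptx3 among them, and 14 did not pass. Klf4, Ckb and Abcc3 fell there (differences between genotypes of 1.94, 1.67 and 1.51, the last 2 named after their values were seen). Of the 18 lower genes 3 fell in wild-type spleen, 14 did not pass and Psph rose. In knockout spleen 24 of the 27 rose and 17 of the 18 fell. Averaged over genotypes 22 rose and 17 fell, which a difference in the knockout LPS arrays alone would also raise, so these counts do not show a shared response.

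**Figure D4:**
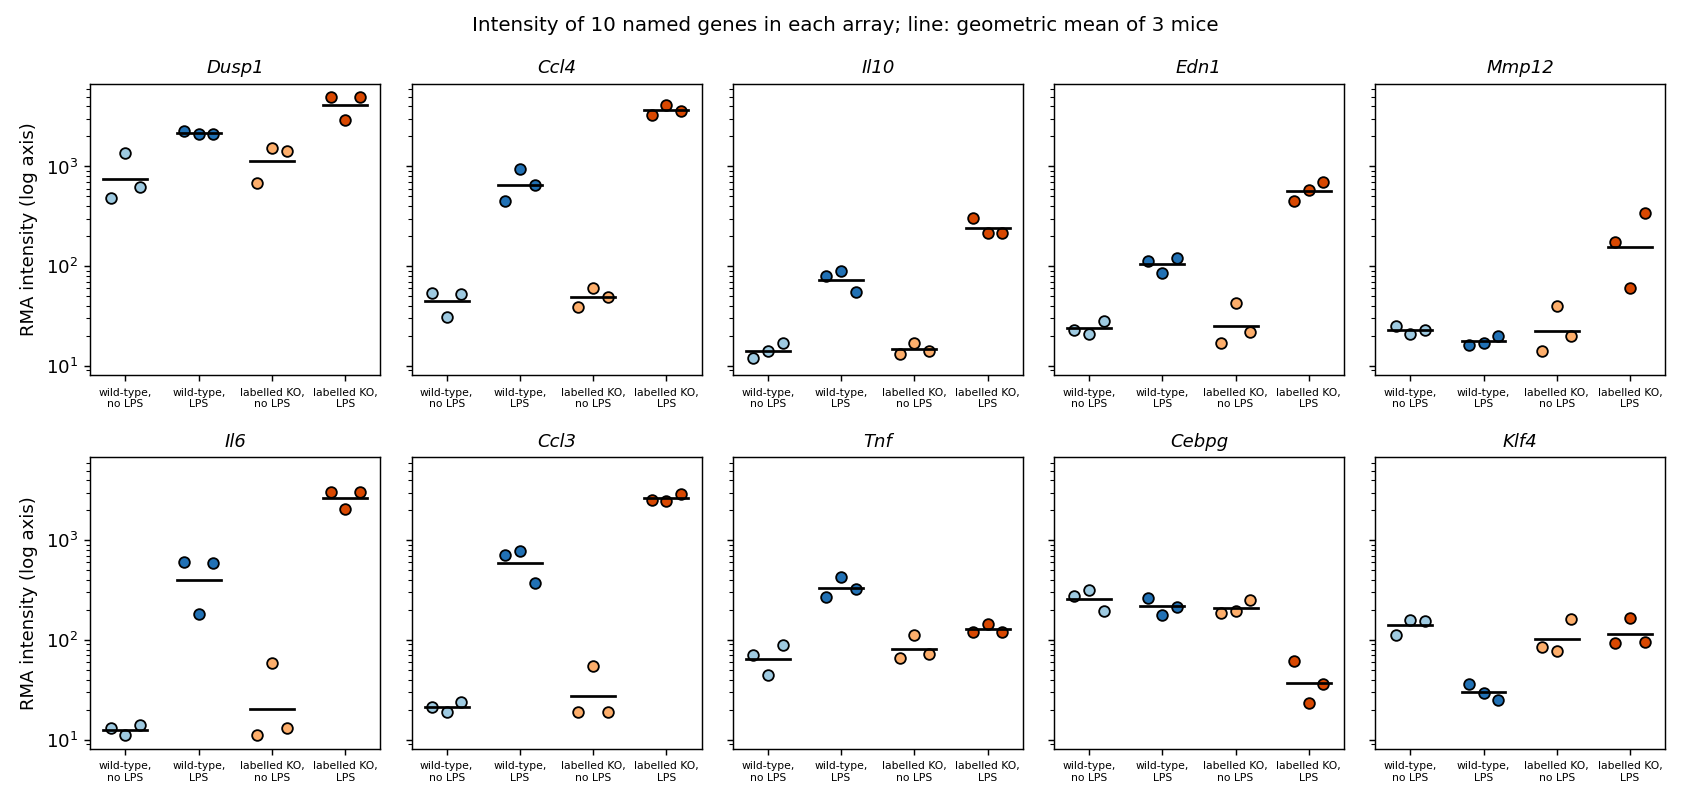
RMA intensity on a log axis (vertical) of 10 named genes in each of the 12 arrays by group (horizontal), with 1 point per array and a line at the geometric mean of 3 mice. Dusp1 stood at 4963, 2948 and 4996 in LPS arrays labelled knockout and at 2248, 2142 and 2116 in wild-type LPS arrays.

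Camera called 15 lists after LPS at the preset correlation, 12 higher and 3 lower in knockout spleen. With an estimated correlation or in directional fry 0 were called. The smallest p was that of coagulation and endothelial activation (2 of 24 passed, 8 higher and 0 lower over the list alone, median 0.66, adjusted p = 3.93e-08, and 0.359 with an estimated correlation), through Edn1 and Plat. It was followed by chemokines (2 of 26 passed, 5 higher and 1 lower over the list alone, median 0.38, adjusted p = 0.000327, and 0.630 with an estimated correlation), through Ccl4 and Ccl12, AP-1 and immediate-early genes (1 of 23 passed, 2 higher and 0 lower over the list alone, median 0.39, adjusted p = 0.000327, and 0.630 with an estimated correlation), through Klf4, and monocyte and macrophage markers (0 of 27 passed, 7 higher and 0 lower over the list alone, median 0.28, adjusted p = 0.000327, and 0.359 with an estimated correlation). Also higher were interferon-stimulated genes (0 of 34 passed, 1 higher and 0 lower over the list alone, median 0.46, adjusted p = 0.00296, and 0.644 with an estimated correlation), proinflammatory cytokines (1 of 23 passed, 5 higher and 1 lower over the list alone, median 0.27, adjusted p = 0.00450, and 0.630 with an estimated correlation), through Lif (1.63 ± 0.20), anti-inflammatory regulators (1 of 22 passed, 2 higher and 0 lower over the list alone, median 0.39, adjusted p = 0.00450, and 0.669 with an estimated correlation), through Il10, and acute phase genes (1 of 24 passed, 2 higher and 1 lower over the list alone, median 0.47, adjusted p = 0.00709, and 0.745 with an estimated correlation), through Ptx3 (2.36 ± 0.34). In that order of values, antioxidant genes (0 of 20, 4 and 0, 0.39, 0.00450 and 0.630) were higher too. So was matrix remodelling (1 of 20, 5 and 0, 0.34, 0.00676 and 0.630), through Mmp12. MHC class II (0 of 11, 0 and 0, 0.42, 0.0160 and 0.630) followed. The last were mesothelial and epithelial markers (0 of 11, 0 and 0, 0.37, 0.00829 and 0.630). Mixed fry, for changes in either direction, passed chemokines (adjusted p = 4.8e-07), coagulation (5.1e-05) and others, not interferon-stimulated genes (0.268). Lung transcripts were high in knockout LPS 1 and 3 and liver transcripts in knockout LPS 2 and 3 and wild-type LPS 2. With their list means as covariates the proinflammatory, anti-inflammatory, AP-1, acute phase, MHC class II, matrix and oxidative phosphorylation calls were lost (adjusted p from 0.106 to 0.817). Heat shock was lost too (0.0729), but with a larger mean (-0.33 in place of -0.29). Lower were cell cycle (0 of 26 passed, 0 higher and 0 lower over the list alone, median -0.31, adjusted p = 0.0403, and 0.780 with an estimated correlation), heat shock (0 of 21 passed, 0 higher and 1 lower over the list alone, median -0.26, adjusted p = 0.0403, and 0.359 with an estimated correlation) and oxidative phosphorylation (0 of 26 passed, 0 higher and 0 lower over the list alone, median -0.13, adjusted p = 0.0486, and 0.780 with an estimated correlation). Calls lost without 1 array were interferon-stimulated genes without knockout LPS 3 (adjusted p = 0.0590), epithelial markers without wild-type LPS 1 (0.127), MHC class II without wild-type LPS 2 or 3 (up to 0.103) and acute phase without knockout LPS 2 or wild-type LPS 3 (up to 0.131). Cell cycle lost it without knockout LPS 1 or 3, wild-type control 3 or wild-type LPS 2 (up to 0.194), and heat shock without knockout LPS 2, wild-type control 3 or wild-type LPS 1 or 2 (up to 0.124). With liver and lung covariates cell cycle was called the other way (mean 0.37 in place of -0.33, adjusted p = 0.0290). Oxidative phosphorylation lost it without knockout control 1 or 2, knockout LPS 1 or 3, wild-type control 3 or wild-type LPS 2 (up to 0.307). Median, mean and test differed in sign for 4 lists, none called.

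Whether LPS acted differently in the genotypes was tested as the interaction, and limma called 0 genes (smallest adjusted p = 0.164). An unadjusted p under 0.05 was reached by 800 genes, where chance gives 619.7. With a trend and robust prior 1 gene was called, and with cyclic loess, a median shift or array weights 0, with 597, 857, 732 and 1468 genes at that p. The count was 1 without wild-type control 1 and 1 without knockout LPS 2. Fits without the 3 pancreatic or the 2 low-Xist arrays left 1 control of a genotype. The genes named in advance had interactions of 2.37 ± 0.43 for Ccl4 (adjusted p = 0.262), 1.69 ± 0.33 for Il10 (0.272), -1.70 ± 0.41 for Tnf (0.408), 1.83 ± 0.53 for Ptgs2 (0.580) and 1.81 ± 0.56 for Ccl3 (0.660). They were 2.05 ± 0.86 for Il6 (0.899), 1.51 ± 0.64 for Cxcl2 (0.899), 0.98 ± 0.58 for Ccl2, 0.98 ± 0.82 for Il1b, 0.95 ± 0.66 for Socs3, 0.32 ± 0.58 for Dusp1, 0.17 ± 0.34 for Nos2 and -0.82 ± 0.51 for Ifng (adjusted p = 1 for these last 6). So the Tnf call in wild-type and its absence in knockout spleen did not amount to a shown difference, and neither did the falls of Slc40a1 (3.08 ± 0.88, adjusted p = 0.571), the iron exporter gene, a comparison made after its values were seen. Camera nevertheless called 16 lists at the preset correlation, 14 with a more positive response in knockout spleen and 2 with a more negative one, of which 0 held with an estimated correlation (lowest adjusted p = 0.355) or in fry. Chemokines, coagulation and endothelial activation, MHC class II and macrophage markers were called in every fit with 1 array left out. The count of lists was 7 without knockout control 1 and 10 without wild-type control 3. Calls lost without knockout control 1 were NF-kB (adjusted p up to 0.914 over the fits), AP-1 (0.115), anti-inflammatory (0.0605), acute phase (0.765), proinflammatory (0.295), glucocorticoid (0.771), endothelial (0.428), matrix (0.0918), cell cycle (0.3004) and oxidative phosphorylation (0.472). The cell cycle mean of -0.55 (-0.82 with the red cell mean as a covariate) turned to 0.16 in that fit. It was 0.25 without the 3 control arrays with pancreatic transcripts. The glucocorticoid mean of 0.33 turned to -0.34 without the 2 low-Xist controls. Antioxidant genes lost it without knockout control 2 or wild-type control 2 (up to 0.230). Interferon-stimulated genes lost it without knockout LPS 3, wild-type control 2 or wild-type LPS 2 or 3 (up to 0.771). Mixed fry passed some, such as chemokines (adjusted p = 0.0048), but not all (interferon-stimulated genes, 0.752).

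Among the 1056 genes that rose with LPS, 593 (56.2%) had the larger response in knockout spleen, with a median interaction of 0.14 (median responses 1.13 and 1.24 in wild-type and knockout). Among the 1777 that fell, 1250 (70.3%) had the larger fall there, with a median interaction of -0.27 (-0.86 and -1.17). After cyclic loess these shares were 62.2% and 65.8%, and with arrays shifted to 1 median 63.5% and 63.4%. The slope of the interaction on the averaged response was 0.17 ± 0.13 (jackknife standard error over arrays), from 0.073 to 0.21 with 1 array left out. It turned to -0.0758 without the 2 low-Xist controls, with pancreas-rich wild-type control 1 alone left. Genes are not independent replicates, and 5 of 100 regroupings of the genotype labels, the real one included, gave a slope as far from 0.

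Averaged over both treatments, knockout against wild-type spleen gave 0 calls by limma (711 genes at an unadjusted p under 0.05, chance 619.7, smallest adjusted p = 0.126). The trend and robust prior, loess, median shift and weights also gave 0, with 614, 724, 683 and 851 genes at that p, and leaving out wild-type control 1 or knockout LPS 2 gave 1. Fits without the 3 pancreatic or the 2 low-Xist arrays again left 1 control of a genotype. Camera called 13 lists, 9 higher and 4 lower, and 0 held with an estimated correlation (lowest adjusted p = 0.117) or in fry. The lowest p belonged to coagulation and endothelial activation (median 0.22, adjusted p = 9.27e-05, and adjusted p = 0.634 with an estimated correlation), to epithelial markers (0.30, 0.000958, and adjusted p = 0.634 with an estimated correlation) and, lower, to heat shock (-0.25, 0.00150, and adjusted p = 0.117 with an estimated correlation). The count was 8 without wild-type control 1 and 8 without wild-type LPS 3. Without the first of these, AP-1 (adjusted p up to 0.168 over the fits), acute phase (0.198), antioxidant (0.653), matrix (0.253), interferon-stimulated (0.153), proinflammatory (0.0621) and ribosomal (0.356) calls were lost (with liver and lung covariates the AP-1 mean turned from 0.24 to -0.045), and B cells (0.0969) without knockout control 1. A targeted gene often brings flanking sequence from its source strain, so genes near Dusp1 were counted among the 100 with the smallest p. Within 20 Mb lay 9 (3.22 by chance, one-sided Fisher's exact adjusted p = 0.00739), within 10 Mb 6 (2.50, adjusted p = 0.0396) and on the chromosome 12 (4.82, adjusted p = 0.00739). The 9 were Thbs2 (0.82), Pim1 (1.06), Srrm2 (1.04), Gfer (-0.89), Dnah8 (1.35), Baiap3 (-0.63), Cacna1h (-0.69), Mrpl18 (-0.52) and Fam120b (-0.65), a kinase, a splicing factor and a calcium channel gene among them. None passed singly in this average (adjusted p from 0.137 to 0.648), though Thbs2 was 1 of the 45 genes called after LPS, the only 1 within 20 Mb, and they were named after their values were seen. The count within 20 Mb was 2 with liver and lung covariates (exact p = 0.838), 6 without dim probe sets (exact p = 0.145) and 6 without the 3 control arrays with pancreatic transcripts (exact p = 0.104). It was 5 without knockout control 3 (p = 0.221) and 6 without knockout LPS 1 (p = 0.104, both by the exact test).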

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

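The tests of pancreas tissue as the source, of a genotype difference already present without LPS, and both tests of the Dusp1 signal were chosen after the result was seen. So were the list of nuclear-retained transcripts, the liver and lung lists and the fits that leave out 3 arrays or use covariates, and the limits below which a small shift or a count of 0 was taken as no test. The word knockout means the label throughout.

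Pancreatic transcripts stood out in 3 control arrays. The excess over the other 9 arrays correlated across the 17 list members with r = 0.966 between wild-type control 1 and knockout control 1, and 0.891 between wild-type control 1 and knockout control 3, and 15 of the 17 members lay above the other 9 arrays in all 3. The 2 that did not were the islet hormone genes, Ins2 (45, 41 and 27 against 23 to 43) and Gcg (8, 8 and 8 against 8 to 10). The median excess on the log2 scale was 8.05, 6.57 and 3.58. Genes are not independent replicates, but the shared profile is consistent with exocrine pancreas tissue carried into these samples, for which the design gives no biological alternative that was tested. The 3 arrays were then left out, leaving 1 knockout control. Called genes kept 99.2% of their median LPS change in wild-type (median single gene 99.03%, quartiles 92.8 to 105.9%). They kept 103.3% in knockout spleen (102.5%, 83.6 to 122.3%). The typical change did not rest on those arrays. Medians of genes called with them in can hide a subset, so pancreas stays open for some calls.

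The 45 genes called between genotypes after LPS had a median difference of 1.69 in the direction of the call and of 0.042 without LPS, or 2.47% (quartiles -6.26 to 7.28%), which argues against a difference already present, with 28 in the same direction. With the liver and lung means as covariates they kept 98.4% of the median (99.2% for the median single gene, quartiles 93.5 to 109.5%), and 22 were still called. With the mean of the nuclear-retained transcripts, which was 8.61, 7.69 and 8.999 in knockout LPS and 9.34, 7.90 and 8.25 in wild-type LPS arrays, they kept 100.9% of the median, but that covariate moved the median gene on the array by 0.011, so it was no test and such an axis stays open. The 10 splits of 6 arrays are too few for a share under 0.05 (45 genes in the real split, highest other 1). What underlies these genes stays open: the interaction called 0 genes, so a stronger LPS response was not shown for them. The effects of day and litter were not tested, and all 6 LPS arrays had the female pattern of Xist.

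Dusp1 signal in LPS arrays labelled knockout lay above that in wild-type ones. Labels given without regard to genotype were argued against, since 3 of 100 regroupings placed as many genes within 20 Mb of Dusp1 among the 100 smallest p (9 in the real one, highest other 10), although that count fell to 5 without knockout control 3, 6 without knockout LPS 1 and 2 with liver and lung covariates. With those covariates the Dusp1 difference kept 44.04% (7.46 to 80.6%, 0.95 ± 0.41 before and 0.42 ± 0.35 after), so tissue content and genotype cannot be told apart for this gene. A transcript of the altered gene that the probes still detect may be a further source, which no value here tests.

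Counts under other splits of the arrays were compared with the real ones. Comparisons within 6 arrays allow 10 splits, too few for a share under 0.05: genes numbered 1002 in wild-type LPS (highest other 145, 1 split as high), 1889 in knockout LPS (0, 1 split) and 0 in controls (20, and 10 splits reach 0 by definition), and 1 split gave as many as the 45 after LPS. Lists numbered 19 (19, 2 splits), 19 (23, 4 splits), 12 (16, 6 splits) and 15 after LPS (18, 2 splits). For the LPS response averaged over genotypes, 1 of 100 splits gave as many as 2833 genes (highest other 112), so chance was excluded, but 8 of 100 gave as many as 21 lists (24). With 0 genes called, the interaction (highest other 20) and the averaged genotype difference (915) gave nothing to test, since 100 of 100 splits reach 0 by definition. Chance was not excluded for their lists, 16 in 20 of 100 (24) and 13 in 26 of 100 (27). A split that called 915 genes points to a structure of the samples, and what it follows was not tested. The slope of the interaction on the averaged response, 0.166, was matched by 5 of 100 regroupings (highest other 0.183), so chance was not excluded.

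The interaction was called for 16 lists at the preset correlation, of which 0 held with an estimated correlation or in directional fry. That call alone flagged them, and 20 of 100 splits gave as many lists. Median interactions were 0.39 for proinflammatory cytokines, 0.41 for chemokines, 0.50 for anti-inflammatory regulators, 0.41 for interferon-stimulated genes, 0.18 for the NF-kB pathway and 0.26 for AP-1 genes. They were 0.30 for acute phase genes, 0.61 for coagulation and endothelial activation, 0.59 for MHC class II, 0.40 for glucocorticoid response, 0.27 for antioxidant genes and 0.47 for macrophage markers. Endothelial markers had 0.25, matrix remodelling 0.40, cell cycle -0.53 and oxidative phosphorylation -0.34. The cell cycle mean turned from -0.55 to 0.16 without knockout control 1 and 0.25 without the 3 pancreatic arrays, where that of oxidative phosphorylation shrank to -0.00891, and the glucocorticoid mean to -0.34 without the 2 low-Xist arrays. For Mmp12 and Rcan1 every wild-type LPS array lay below and every knockout LPS array above the controls of its genotype, a comparison of arrays that tests no difference. Their interactions of 3.17 and 2.20 did not pass (adjusted p = 0.412 and 0.252), and neither did the wild-type changes of -0.38 and -0.42, at a background level for Mmp12. Poly-A spike controls, outside the comparisons, read 732.3 in knockout LPS 2 and 210.8 in wild-type LPS 2, above the highest control array (196.7).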

How the results depend on the processing

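Alternatives without 3 or 2 control arrays, with covariates, and with other list tests were chosen after seeing the data, and the cause was not tested for any change below unless fewer probe sets or a stricter limit made it by construction. Of the alternative values of named genes 6610 kept direction and side of the threshold, 618 lost it, 24 gained it and 10 reversed. For lists, by the direction of the test, these numbers were 2296, 325, 0 and 16, and of the values that answer a comparison 377 held, 78 moved, 5 lost the threshold and 1 reversed. Leaving out 1 array at a time, genes called ran from 389 to 1290 in wild-type LPS, 988 to 2018 in knockout LPS, 2086 to 3072 averaged, 3 to 68 between genotypes after LPS, and 0 to 1 in controls, for the interaction and for the averaged genotype difference. Lists called ran from 13 to 22, 16 to 19, 18 to 22 and 12 to 16 in that order, from 3 to 20 in controls, 7 to 20 for the interaction and 8 to 16 for the averaged genotype difference. Of genes higher after LPS in knockout spleen 71.43 to 100% rose with LPS, and of lower ones 44.44 to 100% fell, in an average that takes in the difference itself. The slope ran from 0.0730 to 0.210 and genes within 20 Mb of Dusp1 from 5 to 11. Also with 1 array left out, list means ran from -0.346 to 0.195 for anti-inflammatory regulators, -0.473 to 0.104 for the NF-kB pathway and -1.91 to 0.416 for erythroid markers in controls, and -0.931 to 0.161 for cell cycle in the interaction, while the interaction ran from -0.113 to 0.637 for Dusp1 and -0.0443 to 0.405 for Nos2. The trend and robust prior gave 1 interaction gene. Cyclic loess gave 3 lists in controls and reversed the test direction, not the mean (-0.00332), of ribosomal proteins there. Without dim probe sets there were 7 lists in controls, 27 genes after LPS and 6 genes near Dusp1 (exact p = 0.145). Array weights gave 1890 genes in wild-type LPS and 1280 after LPS between genotypes. A 2-fold minimum left 1571 averaged LPS genes. A limit of 0.01 left 379, 828, 1601 and 3 genes in wild-type, knockout and averaged LPS and between genotypes after LPS. The replicate block, though nothing shows that numbers pair mice (6 of 18 pairs with 1 number had r over 0.1, from -0.584 to 0.629), gave 12 genes after LPS, of which 100 and 100% of higher and lower ones had risen and fallen. Fits on only the 2 groups compared gave 1012 genes in knockout LPS and 0 after LPS by limma (1861 at an unadjusted p under 0.05). Without the 3 pancreatic arrays, where 1 knockout control is assumed to vary like the others, there were 155 genes in controls, 79 after LPS, 102 for the interaction, 124 averaged and 6 near Dusp1 (exact p = 0.104). That fit reversed Nos2 in knockout LPS (-0.182), the interactions of Il1b (-0.0592), Nos2 (-0.394) and cell cycle (0.254) and, in the test direction but not the mean, the oxidative phosphorylation interaction (-0.00891) and the averaged antioxidant list (0.0521). Liver and lung covariates gave 22 lists in controls and 2 genes near Dusp1 (exact p = 0.838), and reversed Nos2 in wild-type LPS (-0.00251), Il1b after LPS (-0.00182), erythroid markers in controls (0.817), cell cycle after LPS (0.372) and the averaged AP-1 list (-0.0446). The first residual component gave 1658 genes in wild-type LPS and 171 after LPS. Without the 2 low-Xist arrays, where 1 wild-type control is assumed to vary like the others, there were 405 genes in wild-type LPS, 22 after LPS, 3 in controls, 4 for the interaction, 1 averaged, and 5 and 7 lists in controls and the interaction. It reversed Nos2 in wild-type LPS (-0.0247), anti-inflammatory (0.168) and erythroid lists (0.438) in controls, the interactions of Dusp1 (-0.307) and glucocorticoid response (-0.340), and the slope (-0.0758). With an estimated correlation 2, 3 and 3 lists were called for wild-type, knockout and averaged LPS, and 0 in the other 4 comparisons, in which fry also called 0. The number of arrays, 3 per group, and signal near background limit precision: 30.84% of values lay under 20. List tests were not run with the trend and robust prior, weights, only the groups compared, the 2-fold minimum or the limit of 0.01.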

Other observations

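Serpinb2, an inhibitor of plasminogen activators, had the largest difference of any gene called between genotypes after LPS (3.30, adjusted p = 0.00812), at a dim signal that kept it from being named by the rule, and it is named after its values were seen. The ratio of 3' to 5' actin probe sets was 2.77 in wild-type control 1 and from 1.20 to 1.91 in the other arrays.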
